A study of Arabidopsis thaliana with 6 samples.

How the data were processed

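The 6 arrays measured RNA from whole, untreated 7-day-old Arabidopsis Col-0 seedlings, 2 biological replicates each of WT, of a line expressing FLAG-SUB1A and of a line expressing FLAG-SUB1C. Per the labels, seeds were stratified for 3 days, plates stood at 23 °C with 16 h of light and 8 h of dark, seedlings were collected at midday, and 100 ng of RNA was labelled for each ATH1 array. The deposited values are log2 probe-set summaries that the authors made with RMA, per the submitters' processing notes, and its version is not given in the sources used here. The deposited table held 22810 probe sets, of which 64 controls were left out and 22746 were tested. The probe table listed a single gene for 13513 of these, several genes for 503 and none for 8730. The number of independent transgenic lines is not given in the sources used here.

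Groups were taken from the sample labels. A linear model was fitted to the log2 values of all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 residual and 5.37 prior degrees of freedom), with the contrasts SUB1A minus WT, SUB1C minus WT and SUB1A minus SUB1C. Tests were two-sided, with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of adjusted p 0.05, and "rose", "fell", "higher" and "lower" name values past it unless stated otherwise. SE is the standard error of the contrast in that fit, which pools the spread of the 3 groups, and the arrays were not pooled. Group means under 5, the level of the dim filter, were read as near background, a use chosen after seeing the data, and changes of called genes from them as lower bounds. The deposited table has no detection calls, so changes from or to levels a little above 5 can be compressed too.

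The fixed gene lists numbered 28 and held 420 genes, of which 62 were measured by a probe set with a single listed gene, the brightest one where a gene had several. The 11 lists with at least 3 measured genes were tested by camera in limma with a preset inter-gene correlation of 0.01, adjusted over these lists. Counts of list members use the adjustment over all probe sets, and counts adjusted over the list alone stand beside them. The lists of group VII ERF genes, abscisic acid response, jasmonate, brassinosteroid, senescence, phosphate starvation, cell cycle and seed storage had 0 measured genes and were not analysed here, and separate lists of 13 seed storage and 20 abscisic acid-responsive genes were added after seeing the data for the closing section. Ethylene synthesis and signalling, circadian clock, salicylate, reactive oxygen, heat shock, touch, glucosinolate, iron deficiency and reference genes had 1 or 2 and were given as values.

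The genes named in the report were chosen by a rule. For each comparison these were the 6 largest rises and 6 largest falls among called single-gene probe sets whose arrays did not overlap between groups. To these were added the 2 members with the largest change in each of the 6 lists with the most called members, and PDF1.2, while other genes fixed by name lacked a probe set with a listed gene. Other list members are given to show what a list's count holds. These lists, tests, thresholds and most of the alternatives were chosen before the data were examined. The shared response was the number of probe sets called in both comparisons with WT in the same direction, beside the number that independence gives and beside simulated unchanged groups sharing the WT arrays.

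The arrays were checked for quality. Correlations between arrays of different groups were at most 0.996, and the 3' minus 5' difference of the actin control lay between 2.24 and 2.51. The fit was tested on simulated data with 50 probe sets changed at each size. There it recovered 2% at a log2 change of 0.25, 76% at 0.5, 98% at 1 and 100% at 2. Far fewer probe sets were changed there than were called in the data, which makes the adjusted threshold stricter, so these shares do not carry over directly. The median absolute log2 change of called probe sets was 0.38 for SUB1A against WT, 0.44 for SUB1C against WT and 0.41 for SUB1A against SUB1C. Small changes can still be missed at this number of arrays. Replicate numbers are shared between groups, and the deviations of arrays with the same number had correlations of -0.01, 0.04 and 0.02. Alternatives were a replicate block, only the 2 groups compared, renewed quantile normalization, median centring, filters on dim or several-gene probe sets, trended or robust moderation, array weights, other thresholds and leaving out each array. For lists they were an estimated correlation, fry, filtered genes and the mean of a gene's probe sets. Leaving out organelle genes, and comparing each line with a different WT array, were added after seeing the data. The pseudocount for linear values was not used here, since the values are log2.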

Results

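RNA from whole 7-day-old Arabidopsis thaliana Col-0 seedlings was hybridised to Affymetrix ATH1 arrays, with 2 arrays from 2 biological replicates in each of 3 groups. The groups were untransformed wild type (WT), seedlings expressing FLAG-tagged SUB1A and seedlings expressing FLAG-tagged SUB1C, both rice transcription factors of the ethylene response factor (ERF) family driven by the constitutive 35S promoter. No treatment was applied, and the labels list no line carrying an empty vector. The number of independent transgenic lines is not given, so effects of a transgene were not separated from other differences between the lines. The SE does not cover variation between independent lines. Expression is given as log2 values, and changes as differences of group means ± the standard error (SE) of the limma fit, with n = 2 arrays per group. The small number of arrays limits the precision of every value. Across probe sets, which are not independent replicates, the correlation between the 2 arrays of a group was 0.998 in WT, 0.998 in the SUB1A line and 0.999 in the SUB1C line, against 0.989 to 0.992 between WT and SUB1A arrays and 0.995 to 0.996 between WT and SUB1C arrays. The levels of the rice transgenes themselves were not analysed here.

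The comparison of the SUB1A line with WT asked which transcripts differed in untreated seedlings of that line. Genes of late embryogenesis abundant (LEA) proteins, known from seeds and water-stressed tissue, gave the 3 largest rises among the named genes. M17 rose to 8.31 from 4.15, which lies close to the lowest values of the arrays (3.76 to 3.85), so that its change of 4.16 ± 0.11 or 17.9-fold is a lower bound. AT3G02480 rose by 3.57 ± 0.07 and AT3G15670 by 3.04 ± 0.10. The beta-glucosidase gene BGLU19 rose by 3.03 ± 0.20, the leucine-rich repeat kinase gene AT1G35710 by 2.78 ± 0.12 and AT3G47380, of the pectin methylesterase inhibitor family, by 2.65 ± 0.07. The largest falls were those of the thionin genes AT1G66100, 5.80-fold lower at -2.54 ± 0.09, and THI2.2, at -2.48 ± 0.12, which encode small antimicrobial peptides. AT1G26250, an extensin-like gene, fell by 2.38 ± 0.20, the lipid transfer protein gene AT4G12500 was 4.27-fold lower, and AT3G54040, of the PAR1 family, changed by -1.92 ± 0.12. The defensin gene PDF1.2b fell by 2.03 ± 0.39, read by a probe set of a type that can cross-hybridise, and its adjusted p of 0.00740 became 0.0641 with robust moderation. Its change was -2.80 without WT replicate 1 and -1.26 without WT replicate 2. By the rule that chose them, each of these 12 genes passed the threshold and had both SUB1A arrays on the same side of both WT arrays. Their adjusted p was at most 0.00740 from limma with Benjamini-Hochberg adjustment.

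The measured genes of the cold and dehydration list, 4 of 20, fell in the SUB1A line. Of the 4 measured genes on that list, 4 fell (4 adjusted over the list alone), with COR15B at -1.80 ± 0.18, COR15A at -1.49 ± 0.23, COR47 at -0.55 ± 0.10 and LTI30 at -0.37 ± 0.08. The list was lower as a set by camera with adjusted p = 0.000497, and the call was lost at adjusted p = 0.338 with an estimated correlation. Among auxin response genes 3 of 4 fell (4 adjusted over the list alone), including the auxin-conjugating GH3.3 at -1.32 ± 0.17 and the Aux/IAA gene IAA29 at -0.48 ± 0.09, with a set adjusted p = 0.00190 that became adjusted p = 0.338 with an estimated correlation. Flavonoid and anthocyanin genes fell in 3 of 4 cases (3 adjusted over the list alone). Of these, DFR, an enzyme of the anthocyanin pathway, changed by -0.79 ± 0.10, the glycosyltransferase gene UF3GT by -0.64 ± 0.10 and AT4G14090 by -0.64 ± 0.08. The set's adjusted p was 0.00147, and adjusted p = 0.338 with an estimated correlation.

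Cell wall loosening genes moved both ways in the SUB1A line, with 3 of 9 higher and 3 lower (3 and 4 adjusted over the list alone). The expansin genes EXPA8 and EXPA15 fell by 1.83 ± 0.08 and 0.89 ± 0.09, whereas the xyloglucan endotransglucosylase genes XTH18 and XTH19 rose by 0.66 ± 0.07 and 0.63 ± 0.06. The set gave adjusted p = 0.455 by camera and 0.00303 by fry in either direction. In the gibberellin list, with 5 of 30 genes measured, 3 of 5 genes rose (3 adjusted over the list alone). These were the receptor genes GID1A, at 0.29 ± 0.06, and GID1B, at 0.38 ± 0.07, and SLY1, an F-box gene of DELLA protein turnover, at 0.51 ± 0.08. The gibberellin set gave adjusted p = 0.0797 by camera and 0.0250 by fry. In the starch and sugar list AMY1 rose by 0.49 ± 0.09 while APL3 and DPE1 fell by 1.08 ± 0.18 and 0.43 ± 0.06, so 1 of 3 was higher and 2 lower (the same counts adjusted over the list alone), with a set adjusted p = 0.318. Of the root markers, the root hair expansin genes EXPA7 and EXPA18 rose by 0.29 ± 0.08 each, and PYK10 changed by 0.11 ± 0.06, which did not pass. That is 2 of 3 higher (2 adjusted over the list alone), with a set adjusted p = 0.0797 by camera and 0.0294 by fry.

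The hypoxia response list held 8 measured genes, of 23 listed, in the SUB1A comparison. Of these 0 rose and 1 fell (0 adjusted over the list alone), the fall being AT4G17260, a lactate dehydrogenase gene, at -0.33 ± 0.10, while the pyruvate decarboxylase gene PDC2 changed by 0.15 ± 0.07 without passing. The hypoxia set gave adjusted p = 0.638, with a positive test direction, median and mean. Ethylene and jasmonate defence genes were 1 of 3 higher and 1 lower (1 and 1 adjusted over the list alone), with THI2.1 at 0.34 ± 0.08 and a set adjusted p = 0.522. PDF1.2, fixed in advance, changed by -0.56 ± 0.27 with adjusted p = 0.194, and its WT arrays had a standard deviation of 0.74. Without WT replicate 1 its change was -1.08 with adjusted p = 0.00185, and without WT replicate 2 it was -0.03 with adjusted p = 0.880. Flowering time genes, with 5 of 33 measured, were 0 of 5 higher and 1 lower (1 adjusted over the list alone), SNZ at -0.45 ± 0.10. The flowering set gave adjusted p = 0.713 with a positive median of 0.04 and a negative mean of -0.05. Nuclear photosynthesis genes were 0 of 3 higher and 1 lower (1 adjusted over the list alone), LHCB4.2 at -0.35 ± 0.07. The photosynthesis set gave adjusted p = 0.221 by camera and 0.0294 by fry.

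Lists with 1 or 2 measured genes were not tested as sets. In the SUB1A line STZ, a zinc finger gene on the reactive oxygen and touch lists, rose by 0.86 ± 0.15, and GRX480 of the salicylate list rose by 0.61 ± 0.06 while SAG101 changed by 0.19 ± 0.09 without passing. BCAT4, an enzyme of methionine chain elongation for glucosinolates, fell by 1.02 ± 0.07, and the glucosinolate gene UGT74B1 rose by 0.26 ± 0.07. EIN3 of ethylene signalling changed by 0.00 ± 0.06, the clock gene GI by -0.07 ± 0.06 and the iron deficiency gene BHLH101 by -0.03 ± 0.10, none of them past the threshold. The heat shock genes ATHSP22.0 and AT1G53540 changed by 0.19 ± 0.06 and 0.06 ± 0.06, and the reference genes PEX4 and AT4G34270 by -0.06 ± 0.07 and 0.16 ± 0.06, all short of the threshold over all probe sets. ATHSP22.0 passed when adjusted over the list alone. ADH1, PDC1, FT, CO, FLC and GA20OX1 were not analysed here.

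Across all 22746 probe sets, limma with Benjamini-Hochberg adjustment found 4606 changed at adjusted p under 0.05 in the SUB1A line, 2154 higher and 2452 lower, and after median centring 2310 of 4622 were higher. At least a 2-fold change was seen for 283 of them, 183 higher and 100 lower. Of the 4606, 2386 named a single gene. Among probe sets for which no gene was listed, the largest rise was 4.57 ± 0.19 and the largest fall -3.19 ± 0.29. The count moved by over 1.5 times when 1 array was left out, to 2871 without WT replicate 1 and 2701 without SUB1A replicate 1.

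**Figure D1:**
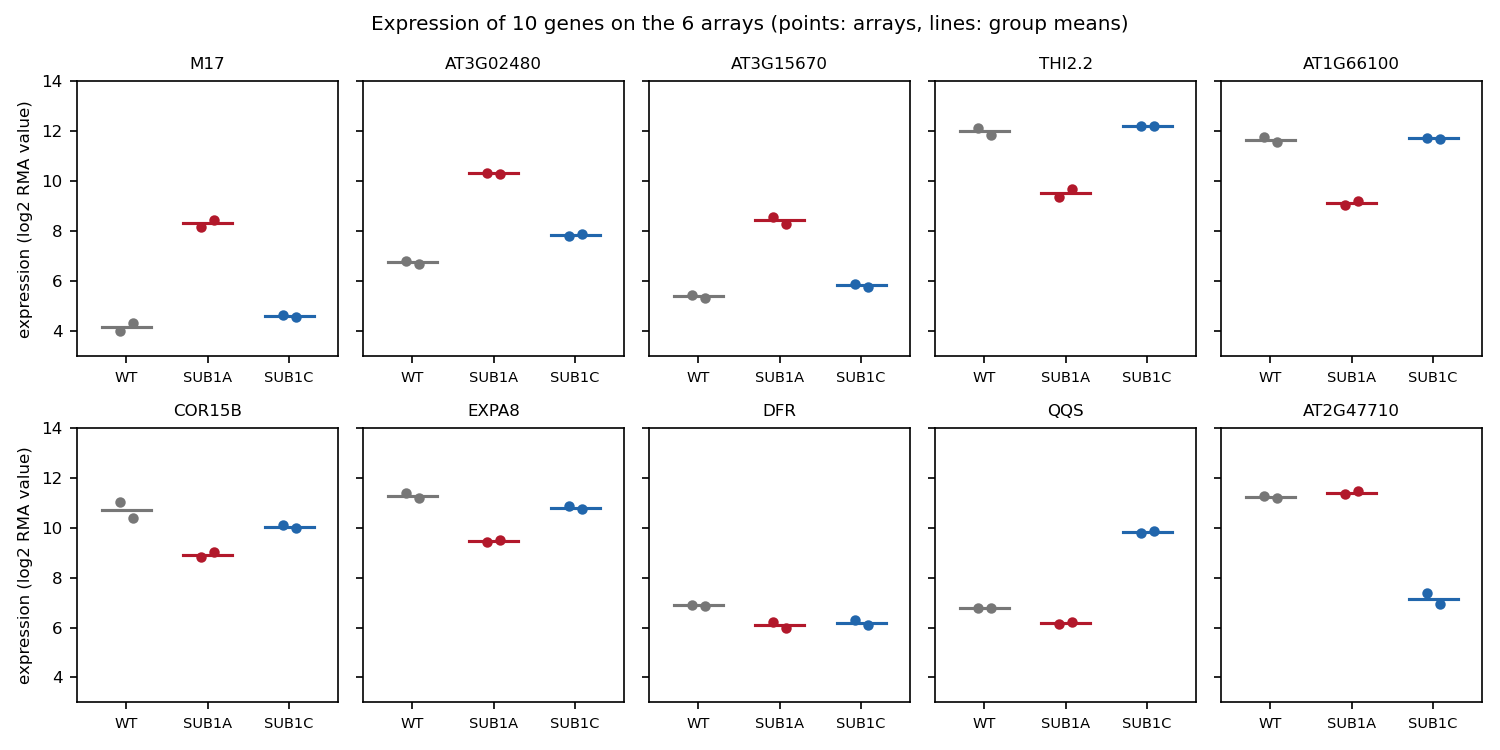
Expression of 10 genes on each of the 6 arrays, as log2 values, with points for arrays and lines for group means. M17, AT3G02480 and AT3G15670 were highest in the SUB1A line, THI2.2, AT1G66100, COR15B and EXPA8 were lowest there, DFR was lower in both lines than in WT, and QQS and AT2G47710 stood apart in the SUB1C line.

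The comparison of the SUB1C line with WT asked the same of the SUB1C line. QQS, an orphan gene known for its effect on starch content, rose from 6.78 to 9.82, a change of 3.04 ± 0.06 or 8.20-fold. AT2G47710, of the universal stress protein family, fell from 11.22 to 7.16, a change of -4.06 ± 0.13 or 16.6-fold lower. The next largest rises were those of AT1G26390 at 1.54 ± 0.31, the germin-like gene AT5G38910 at 1.35 ± 0.28, AT5G54370 at 1.31 ± 0.08, the chitinase family gene AT2G43590 at 1.28 ± 0.07 and AT5G23840 at 1.16 ± 0.09. The next largest falls were those of the beta-glucosidase gene BGLU28, 2.14-fold lower, the plastid gene petG, for a cytochrome b6f subunit, at -1.02 ± 0.18, AT1G20070 at -0.89 ± 0.20, AT5G22580 at -0.85 ± 0.09 and AT4G12500 at -0.85 ± 0.13. The AT1G20070 change was -0.56 without WT replicate 1 and -1.21 without WT replicate 2. By the rule that chose them, each of these 12 genes passed the threshold and had both SUB1C arrays on the same side of both WT arrays. Their limma adjusted p was at most 0.0457.

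Flavonoid and anthocyanin genes fell in the SUB1C line in 3 of 4 cases (4 adjusted over the list alone), with DFR at -0.70 ± 0.10, AT4G14090 at -0.58 ± 0.08 and UF3GT at -0.57 ± 0.10. The set's camera adjusted p was 5.97e-05, and adjusted p = 0.337 with an estimated correlation and 0.0679 with fry. Root markers were 2 of 3 higher (2 adjusted over the list alone), with EXPA7 at 0.78 ± 0.08 and EXPA18 at 0.75 ± 0.08 beside PYK10 at 0.09 ± 0.06, which did not pass. The root set's adjusted p was 0.000339, and adjusted p = 0.299 with an estimated correlation. Cell wall loosening genes were 2 of 9 higher and 1 lower (3 and 1 adjusted over the list alone), with XTH19 at 0.65 ± 0.06, XTH18 at 0.61 ± 0.07 and EXPA8 at -0.47 ± 0.08, and a set adjusted p = 0.342. In the starch and sugar list DPE1 fell by 0.35 ± 0.06, making 0 of 3 higher and 1 lower (2 lower adjusted over the list alone), with a set adjusted p = 0.0929. BCAT4 of the glucosinolate list fell by 0.49 ± 0.07, and UGT74B1 changed by -0.02 ± 0.07 without passing.

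None of the 8 hypoxia genes passed in limma in the SUB1C line over all probe sets or adjusted over the list alone, and their median change was 0.12 with a set adjusted p = 0.0929. The 4 cold and dehydration genes were 0 higher and 0 lower (1 lower, COR15B at -0.67 ± 0.18, adjusted over the list alone), with a set adjusted p = 0.674. The 4 auxin response genes had a median of 0.10 and a set adjusted p = 0.342, and the 5 gibberellin genes had a median of 0.03 and a set adjusted p = 0.674. The 5 flowering time genes had a median of -0.01, and the 3 nuclear photosynthesis genes a median of -0.03, each with a set adjusted p = 0.674. Of the auxin, gibberellin, flowering and photosynthesis genes 0 passed, also when adjusted over the list alone. The 3 ethylene and jasmonate defence genes gave a set adjusted p = 0.685, with PDF1.2 at -0.17 ± 0.27 and adjusted p = 0.780. The PDF1.2 change was -0.70 without WT replicate 1, with adjusted p = 0.0239, and 0.35 without WT replicate 2, with adjusted p = 0.137. GRX480, at 0.17 ± 0.06, passed when adjusted over its list of 2 measured genes but not over all probe sets. STZ, at 0.39 ± 0.15, did not pass over all probe sets. It is the only measured gene of its lists, so adjusting over the list alone leaves its limma p unadjusted. An unadjusted limma p under 0.05 was reached by 4681 of 22746 probe sets.

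In total 1071 of 22746 probe sets changed in the SUB1C line by limma with Benjamini-Hochberg adjustment, 645 higher and 426 lower, and 38 of them changed at least 2-fold, 29 higher and 9 lower. After median centring 740 of 1054 were higher. Among probe sets with no listed gene, the largest rise was 2.64 ± 0.55 and the largest fall -3.05 ± 0.08. The count fell to 585 without WT replicate 1, 618 without WT replicate 2, 191 without SUB1C replicate 1 and 392 without SUB1C replicate 2. The calls of AT1G26390, AT5G38910 and DPE1 ended without any 1 of these 4 arrays, with adjusted p up to 0.219, 0.216 and 0.158, and robust moderation of all arrays also ended those of AT1G26390 (adjusted p = 0.0840) and AT5G38910 (adjusted p = 0.0827). Without SUB1C replicate 1, calls also ended for AT4G12500 with adjusted p = 0.122, BGLU28 with 0.102, petG with 0.146, AT1G20070 with 0.201 and BCAT4 with 0.112. On all 6 arrays the AT1G20070 call also ended with a replicate block (adjusted p = 0.0600), median centring (adjusted p = 0.0516) and robust moderation (adjusted p = 0.0636). Without SUB1C replicate 2, they ended for BGLU28 with adjusted p = 0.107, petG with 0.0855, AT1G20070 with 0.192, BCAT4 with 0.0505, DFR with 0.0611 and AT4G14090 with 0.0647. Without WT replicate 1, they ended for AT1G20070 with adjusted p = 0.137, BCAT4 with 0.0531 and DFR with 0.0550, and without WT replicate 2 for AT4G14090 with 0.0534.

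**Figure D2:**
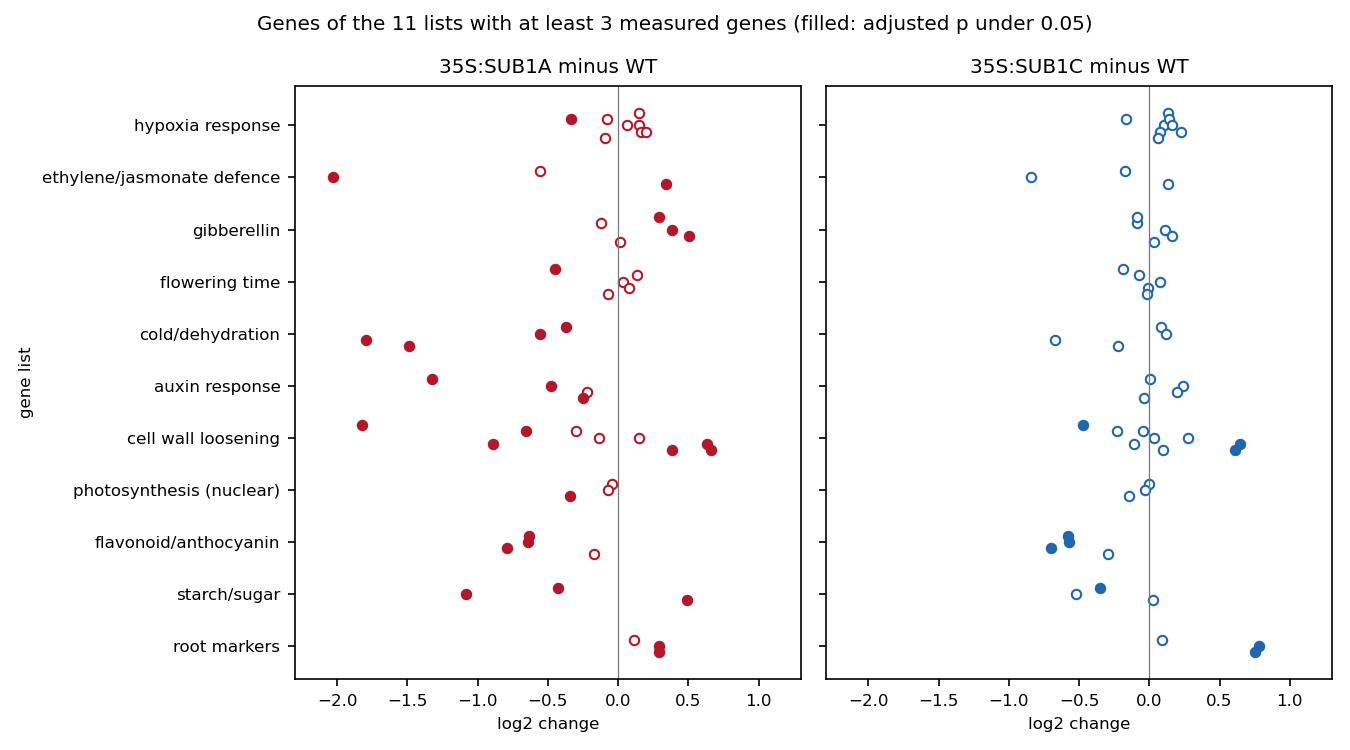
Log2 change from WT of each measured gene in the 11 lists with at least 3 measured genes, for the SUB1A line (left) and the SUB1C line (right), with filled points at adjusted p under 0.05. The 4 cold and dehydration genes lay below 0 and passed in the SUB1A line, 3 of 4 flavonoid and anthocyanin genes passed below 0 in both lines, and 0 of 8 hypoxia genes passed above 0 in either.

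The direct comparison of the SUB1A line with the SUB1C line asked which transcripts differed between these lines, whether through the rice transgenes or not. AT2G47710 was higher in the SUB1A line by 4.25 ± 0.13, M17 by at least 3.70 ± 0.11 over a SUB1C level of 4.61 near the lowest array values, AT3G15670 6.08-fold, AT3G02480 by 2.47 ± 0.07, AT3G47380 by 2.25 ± 0.07 and BGLU19 by 2.23 ± 0.20. QQS was lower in the SUB1A line by a log2 change of -3.64 ± 0.06, 12.5-fold. The thionin genes THI2.2 and AT1G66100 were lower at -2.69 ± 0.12 and -2.59 ± 0.09, AT4G14060 was 4.30-fold lower, and there were also lower values for AT5G38910 at -1.71 ± 0.28 and AT3G54040 at -1.70 ± 0.12. By the rule that chose them, each of these 12 genes passed the threshold and had arrays that did not overlap between the lines. Their limma adjusted p was at most 0.00567, and the call of AT5G38910 ended without SUB1C replicate 1.

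The cold and dehydration genes were lower in the SUB1A line than in the SUB1C line in 4 of 4 cases (4 adjusted over the list alone), with COR15A at -1.26 ± 0.23 and COR15B at -1.13 ± 0.18, and a camera set adjusted p = 5.94e-05. Auxin response genes were lower in 3 of 4 cases (4 adjusted over the list alone), with GH3.3 at -1.33 ± 0.17 and IAA29 at -0.72 ± 0.09, and a set adjusted p = 5.94e-05. Both calls were lost at adjusted p = 0.286 with an estimated correlation. Cell wall loosening genes were lower in 4 of 9 cases (1 higher and 4 lower adjusted over the list alone), with EXPA8 at -1.36 ± 0.08 and EXPA15 at -0.78 ± 0.09. The set's adjusted p was 0.0116, and adjusted p = 0.303 with an estimated correlation, 0.0625 without SUB1A replicate 1 and 0.194 with genes above the median level. Root markers were lower in 2 of 3 cases (2 adjusted over the list alone), EXPA7 at -0.49 ± 0.08 and EXPA18 at -0.46 ± 0.08. The root set's adjusted p was 0.0383, and adjusted p = 0.286 with an estimated correlation, 0.0504 without either WT replicate, 0.0625 without SUB1A replicate 1 and 0.0642 with genes above the median level.

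Gibberellin genes were higher in the SUB1A line than in the SUB1C line in 3 of 5 cases (3 adjusted over the list alone), with GID1A at 0.38 ± 0.06 and SLY1 at 0.34 ± 0.08. The set's adjusted p was 0.0515 by camera and 0.0245 by fry. In the salicylate list GRX480 was higher by 0.43 ± 0.06 and SAG101 by 0.34 ± 0.09. In the glucosinolate list UGT74B1 was higher by 0.27 ± 0.07, and BCAT4 was lower at -0.53 ± 0.07. Calls ended without any 1 of the 4 arrays of these lines for SAG101, with adjusted p up to 0.230, and for UGT74B1, up to 0.185. The SLY1 call ended without SUB1A replicate 1, SUB1A replicate 2 or SUB1C replicate 2, with adjusted p = 0.0841, 0.107 and 0.166. The COR15A call ended without SUB1A replicate 1 or SUB1C replicate 1, with adjusted p = 0.0619 and 0.0814, and the GID1A call without SUB1C replicate 2, with adjusted p = 0.0577. SAG101 also fell short with adjusted p = 0.0505 when moderation followed a trend and adjusted p = 0.0559 with a replicate block. The flavonoid and anthocyanin genes had a median difference of -0.07 and 0 of 4 passed in limma over all probe sets or adjusted over the list alone, with a set adjusted p = 0.819. The hypoxia, flowering time and photosynthesis genes also gave 0 calls, with set adjusted p of 0.335, 0.923 and 0.335. In the starch and sugar list AMY1 was higher, at 0.47 ± 0.09, and 1 higher and 1 lower passed adjusted over the list alone, with a set adjusted p = 0.923, and the ethylene and jasmonate set gave adjusted p = 0.672 with 0 of 3 genes called (1 lower adjusted over the list alone) and PDF1.2 at -0.38 ± 0.27. PDF1.2 passed with adjusted p = 0.0305 when either WT array was left out.

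Between the lines 2742 probe sets differed by limma with Benjamini-Hochberg adjustment, 1268 higher and 1474 lower in the SUB1A line, and 186 differed at least 2-fold, 120 higher and 66 lower. Among probe sets with no listed gene, the largest differences were 3.06 ± 0.08 and -2.04 ± 0.29. The count fell to 1358 without SUB1A replicate 1, 1746 without SUB1A replicate 2, 1078 without SUB1C replicate 1 and 1150 without SUB1C replicate 2.

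**Figure D3:**
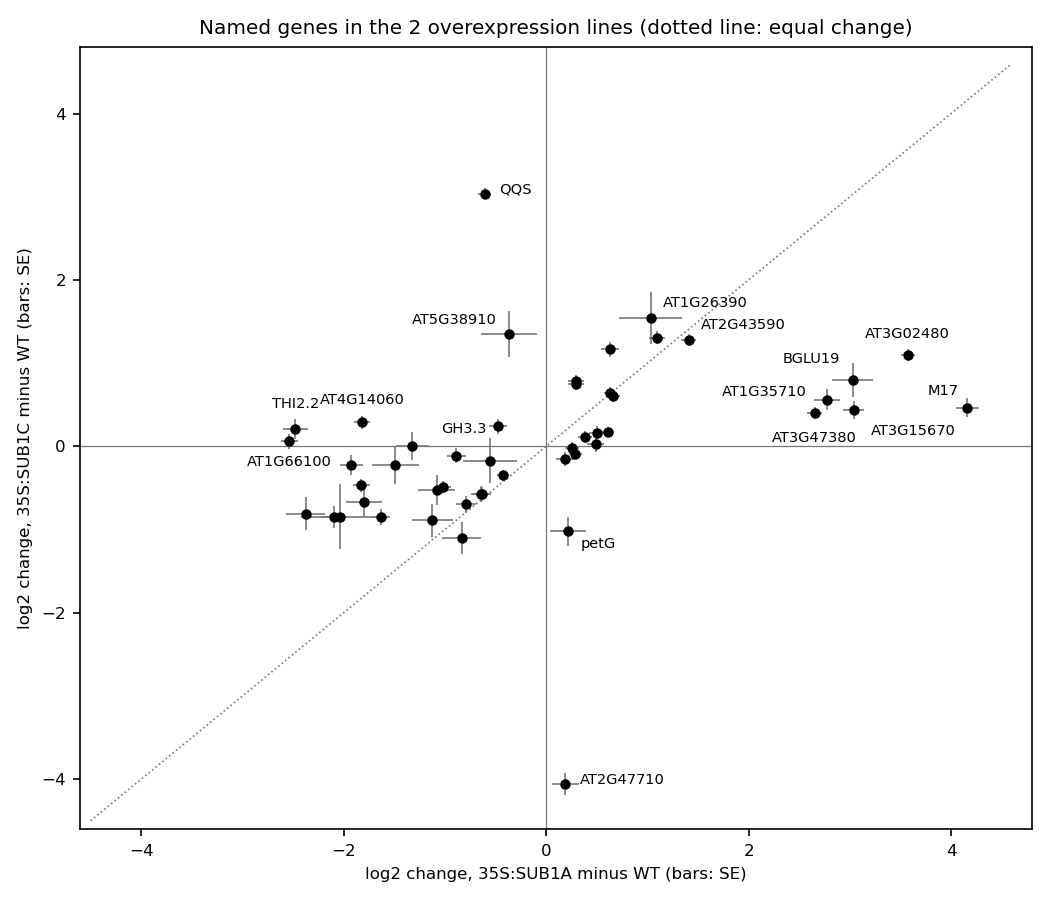
Log2 change from WT of each named gene in the SUB1A line (x axis) and the SUB1C line (y axis), with bars for the SE and a dotted line where both changes are equal. M17 lies at 4.16 and 0.46, QQS at -0.61 and 3.04, AT2G47710 at 0.19 and -4.06, and AT2G43590 close to the dotted line at 1.41 and 1.28.

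Part of the differences from WT were shared by both lines. A departure of the untransformed WT group from both lines would also give such an overlap and was not separated from a response to the transgenes. AT2G43590 was higher than in WT by 1.41 ± 0.07 in the SUB1A line and 1.28 ± 0.07 in the SUB1C line, AT5G54370 was 2.14-fold and 2.47-fold higher, and XTH19 was higher by 0.63 ± 0.06 and 0.65 ± 0.06. DFR changed by -0.79 ± 0.10 and -0.70 ± 0.10, and AT5G22580 by -1.63 ± 0.09 and -0.85 ± 0.09. Of the probe sets called in each line by limma, 385 were higher in both, where independence of the lists would give 61.1, and 339 were lower in both, where it would give 45.9. A further 28 were called in opposite directions, among them QQS at -0.61 ± 0.06 in the SUB1A line. The comparisons share their WT arrays, which alone links them. They also share the estimated spread of each probe set, in the next fits too, so independence can give too low a number. In fits chosen after seeing the data that gave each line a different WT array, with fewer arrays per contrast, 183 were higher and 97 lower in both (32.8 and 16.8 under independence) and 42 opposite with WT replicate 1 for SUB1A, and 230 higher and 151 lower (23.6 and 14.9) and 10 opposite with WT replicate 2 for SUB1A. Across probe sets, which are not independent replicates, the log2 changes had a correlation of 0.54, against a mean of 0.50 and a maximum of 0.51 in 100 simulated draws of unchanged groups with shared controls, and a covariance of 0.0287, against 0.00321. Of the probe sets called in the SUB1A line 85.4% had the same sign in the SUB1C line, against a mean of 83.7% and a maximum of 85.4% in these draws. The draws hold no changed probe sets, so their correlation and share come from the shared WT arrays alone. They do not give what shared controls add where the SUB1A line has changes of its own. Neither the correlation nor the share can therefore decide on an excess. With a different WT array for each line the correlation was 0.30 or 0.51. Of the 724 probe sets called in both lines in the same direction, 184 differed between the lines, with the larger change in the SUB1A line for 147 and in the SUB1C line for 37. The count of 724 fell to 376 without WT replicate 1, 462 without WT replicate 2, 481 without SUB1A replicate 1, 477 without SUB1A replicate 2, 147 without SUB1C replicate 1 and 263 without SUB1C replicate 2.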

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

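The tests of neighbouring genes, single arrays and organelle genes, and the fits of petG without 1 array, in this part were chosen only after the results were seen. For 11 of the 48 genes named by the rule, the effects relative to WT had opposite signs in the 2 transgenic lines, with at least 1 past the threshold, and the direct limma difference of SUB1A minus SUB1C also passed. AT2G47710 changed by 0.19 ± 0.13 in the SUB1A line and -4.06 ± 0.13 in the SUB1C line, a difference of 4.25. QQS changed by -0.61 and 3.04 (difference -3.64), THI2.2 by -2.48 and 0.21 (-2.69), AT1G66100 by -2.54 and 0.06 (-2.59), AT4G14060 by -1.81 and 0.29 (-2.10) and AT5G38910 by -0.37 and 1.35 (-1.71). GH3.3 changed by -1.32 and 0.01 (-1.33), petG by 0.22 and -1.02 (1.24), IAA29 by -0.48 and 0.24 (-0.72), GID1A by 0.29 and -0.09 (0.38) and UGT74B1 by 0.26 and -0.02 (0.27). QQS passed relative to WT in both lines, and the other 10 in 1 line. The differences of these 11 genes were also fitted without each array, and missed the threshold for AT5G38910 (adjusted p = 0.0503 without SUB1C replicate 1), GID1A (adjusted p = 0.0577 without SUB1C replicate 2) and UGT74B1 (adjusted p = 0.0612 and 0.145 without SUB1A replicate 1 and 2, 0.185 and 0.0981 without SUB1C replicate 1 and 2).

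For the fall of AT2G47710 in the SUB1C line, a fault of 1 array is argued against, since the lowest WT array lay 3.79 above the highest SUB1C array. A deletion that includes AT2G47690, the nearest named gene on 1 side, is argued against by its change of -0.32 (95% interval -0.46 to -0.19). A shorter deletion stays open, since the nearest named gene on the other side, AT2G47720, with a change of -0.17, lay near background, and probe sets with no listed gene, whose position is not known here, fell by 3.05 and by a log2 change of -2.48 in this line. Lower expression of the surrounding region stays open: the 10 nearest named genes had a median of -0.15, at percentile 0.272 of 13215 windows, and 2 of them fell, but by far less than AT2G47710. An effect of SUB1C itself may also account for the fall and was not tested.

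The fall of petG went with lower values of plastid-encoded genes in the SUB1C line, with a median of -0.30 over 69 genes (camera adjusted p = 3.08e-14, and adjusted p = 0.648 with an estimated correlation), of which 5 fell. For the fall relative to WT, poorer capture of RNA without long poly(A) tails is argued against by the 16 mitochondrially encoded genes. Their median was 0.11, with a 95% bootstrap interval over genes of -0.03 to 0.17 that leaves out the spread between arrays. Relative to the SUB1A line, plastid-encoded and mitochondrially encoded genes were both lower in the SUB1C line. Their medians for SUB1A minus SUB1C were 0.17 and 0.19 (camera adjusted p = 0.00104 and 0.0243, both 0.661 with an estimated correlation). Against that line poorer capture stays open. No 1 array makes the whole plastid shift relative to WT. The plastid median was, however, -0.18 without WT replicate 1, -0.18 without SUB1C replicate 1, -0.33 without WT replicate 2 and -0.36 without SUB1C replicate 2. Less green tissue could not be excluded. The 3 measured nuclear photosynthesis genes had a median of -0.028 and ranged from -0.14 to 0.00, too few genes to decide. A lower plastid transcript level in this line may be biological, but the explanation by less green tissue stays open.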

How the results depend on the processing

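Leaving out organelle genes and separate WT arrays for each line were chosen after seeing the data. The first gave 4616, 1091 and 2765 changed probe sets for SUB1A against WT, SUB1C against WT and SUB1A against SUB1C, beside 4606, 1071 and 2742. With a replicate block the counts were 4473, 1025 and 2625, and 696 shared beside 724. Renewed normalization, median centring, the filters on dim probe sets, trended or robust moderation and array weights, where run, also gave counts within 1.5 times. Single-gene probe sets alone gave 2318, 588 and 1304, by testing fewer probe sets. A 2-fold minimum gave 283, 38, 186 and 15 shared, and adjusted p under 0.10 gave 2083 for SUB1C and 1371 shared, by construction of the thresholds. Leaving out 1 array, with the lone array assumed to vary like the other groups, gave 2701 to 3961, 191 to 882 and 1078 to 3026 probe sets and 147 to 481 shared, with fewer arrays in each fit. Separate WT arrays gave 280 and 381 shared, also with fewer arrays. Of the tested lists, 3, 2 and 4 passed. With an estimated correlation 0, 0 and 0 passed. With genes above the median level 2 passed for SUB1A, of which 1 was among the 3, 1 for SUB1C, and 2 for SUB1A against SUB1C, of which 1 was among the 4, with fewer genes tested. Fry passed 6 for SUB1A and 1 for SUB1C, and in either direction 7 and 5, where the cause was not tested. For SUB1A fry added gibberellin, photosynthesis and root markers, and in either direction gibberellin, flowering time, cell wall loosening and starch and sugar. For SUB1C fry in either direction added hypoxia, cell wall loosening and starch and sugar. For SUB1A against SUB1C both forms of fry added gibberellin. Without 1 array 3 to 4, 2 to 3 and 3 to 5 lists passed. Among named genes, 379 of the fits without 1 array kept direction and side of the threshold, 42 lost the call and 4 gained it. These fits include those without an array of the group not compared. PDF1.2 in the SUB1C line reversed, ranging from -0.70 to 0.35. Its SUB1C arrays, at 6.73 and 6.74, lay between WT replicate 1 at 6.38 and WT replicate 2 at 7.43. The sign thus depends on which WT array is kept, and what set the WT arrays apart was not tested. Values near background were not separated from absent transcripts, since the deposited table holds no detection calls.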

Other observations

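The gene families and the spike-in comparison in this part were chosen only after the results were seen, while the tests of seed and abscisic acid genes were written before those genes' values were seen, except OLEO3. Of 41 families tested by camera in each comparison, 4 passed in the SUB1A line. UDP-glycosyltransferase genes were higher in the SUB1A line than in WT, 15 of 47 rising and 3 falling (median 0.13, adjusted p = 0.00758, and adjusted p = 0.891 with an estimated correlation). WRKY genes rose in 4 of 6 cases (median 0.57, adjusted p = 0.0104, and adjusted p = 0.891 with an estimated correlation). Mitochondrially encoded genes rose in 7 of 16 cases (median 0.21, adjusted p = 0.00758, and adjusted p = 0.936 with an estimated correlation). In the SUB1C line RALFL (median 0.14, adjusted p = 0.00612), TET (0.12, 0.0113) and TBL (0.10, 0.0171) genes passed as higher, beside the plastid-encoded genes. As single genes 2 of 11 RALFL, 2 of 15 TET and 0 of 22 TBL genes rose. Between the lines XTH (median -0.25, adjusted p = 0.00733), PRA (-0.09, 0.0187), EXPA (-0.06, 0.0407) and ATG (-0.21, 0.0407) genes passed as lower in the SUB1A line. There WRKY (0.54, 0.00104), plastid-encoded (0.17, 0.00104), UDP-glycosyltransferase (0.04, 0.0215), LEA (0.37, 0.0243) and mitochondrially encoded genes (0.19, 0.0243) passed as higher. With an estimated correlation 0 families passed in any comparison, the lowest adjusted p being 0.540.

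LEA genes found by a match on gene names rose in 4 of 7 cases in the SUB1A line and fell in 1. Their median was 0.43 (camera adjusted p = 0.00758, and 0.936 with an estimated correlation). Of the 7, 3 had WT levels under 5, where changes can be compressed. The match left out M17, AT3G02480 and AT3G15670, which rose, and the 4 measured genes of the cold and dehydration list, which fell. It is thus not a count of all LEA genes. Seed or embryo RNA carried over could raise LEA genes. In a seed storage list of 13 genes added for this test, the 8 measured genes had a median change of 0.22. Of these genes 3 rose and 0 fell in limma: AT2G28490 by at least 2.27 from a WT level under 5, AT2G25890 by 2.19 and AT4G36700 by 0.82. The genes that did not pass had WT and SUB1A levels between 4.88 and 5.78, where changes can be compressed, which can hold the median down. The 95% bootstrap interval of the median over genes was 0.03 to 2.19 and leaves out the spread between arrays. The interval leaves this open. A rise of abscisic acid-responsive genes was seen in 1 of 6 measured genes of an added list of 20, AT5G66780 at 0.73 or more from a WT level under 5, while SAG29 fell by 0.55. The 95% binomial interval of the share, 0.421 to 64.1%, counts genes as independent and leaves this explanation open too. An effect of SUB1A on these genes was not separated from either.

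The bacterial poly-A spike-in probe sets were higher on replicate 1 than on replicate 2 for 22 of 24 in WT, 23 in the SUB1A line and 23 in the SUB1C line, with median differences of 0.22, 0.43 and 0.23. These 24 probe sets read only the dap, lys, phe and thr spikes, so they are not independent. All other probe sets had median differences of 0.00 in each group, which RMA normalization gives by itself and which therefore does not show that the RNA was alike.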
